A study of Homo sapiens with 4 samples.

How the data were processed

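RNA sequencing of polyadenylated RNA, with libraries made by an Ion Total RNA-Seq kit, covered 4 libraries, 1 each of HT29 and DLD-1 cells kept for 3 days without serum in DMSO or in LDN-193189. The authors deposited 1 workbook per line with a table of 18329 genes. Per the file headers, its columns hold the raw count of exon, exon junction, intron and gene reads of each library, in total and unique, with reads placed on the hg19 build per the submitters' processing notes. The aligner, the annotation release and the strand of counting are not given in the sources used here, so values of overlapping or antisense genes and of paralogs are uncertain. The authors' RPKM divides total exon reads by exon length and by the library's exon reads, which came to 12854572, 32628254, 27976123 and 29253279 in HT29 with DMSO, HT29 with LDN-193189, DLD-1 with DMSO and DLD-1 with LDN-193189. A further deposited column, a score, is the signed fold of LDN-193189 over DMSO RPKM, and further sheets list the genes the authors selected by that fold and by an RPKM of 3. The column named mock was taken as DMSO, and the line was taken from the name of the workbook. Of each table, 20 further columns, counted over both of its libraries together, were not used. Gene starts are counted from 0 in the tables and are given here from 1, and 14 of 14 mitochondrial genes checked had equal positions in the annotation. The tables give an exon length of 0 for 93 genes.

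Within a line, a gene counted as changed when its ratio of RPKM + 1 was at least 2 (or 1.5), the higher RPKM was at least 3, and the exact conditional binomial 95% interval of the ratio of reads, scaled by library totals, left out 1. These intervals cover counting error only. Overlaps between lines used the 1.5-fold rule and are set beside the product of the counts divided by the genes at the RPKM minimum in both lines. For the model over both lines, edgeR 4.0.16 in R 4.3.3 fitted a quasi-likelihood model with terms for line and treatment to the exon read count of genes passing filterByExpr, 12482 in number, with TMM scaling and Benjamini-Hochberg adjustment. Its common dispersion was 0.0389, a coefficient of variation of 19.7%. Lists were tested in it by fry of limma 3.58.1, adjusted over 28 lists. Within a line, the median log2 ratio of a list's members at an RPKM of at least 1 was placed among 10000 random lists matched on size and expression, for lists of at least 3 such members. Where a group had no reads, a fold is given against a floor of 3 counts over the group. The line term of this model pairs the DMSO and LDN-193189 libraries of each line, the only pairing the labels give. Counts over other splits of the samples need at least 3 libraries per group.

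The genes named were fixed by rule. They were the 8 largest rises and 8 largest falls past 2-fold in each line, the 6 genes per direction with the largest smaller change in both lines, the 8 lowest p per direction at an adjusted p under 0.05 in each model, members of 31 gene lists, and ID1, ID2, ID3, BMP4, SMAD4, DUSP5 and BCL2L11. Some genes that the rule takes are not reported here. The lists, the rules and most alternatives were fixed before the data were examined. CXCL8, JAG1, HIST1H3B, HIST1H4C, HIST1H4H, HIST1H2AE and PECAM1 were in lists but not in the tables under a known name and were not analysed here. Alternatives were pseudocounts of 0.1 and 5, RPKM minimums of 1, 10 and none, TMM and median-of-ratios rescaling of RPKM, no condition on the interval, DESeq2 1.42.0, its size factors in edgeR, no filter on low counts, limma on log2 RPKM + 1, and models without the other term. Unique reads, and log2 ratios less their trend on GC content and exon length, were added after seeing the data. GC content came from the transcripts of GENCODE release 29 by gene symbol, and 96.9% of genes at the RPKM minimum in HT29 and 96.8% in DLD-1 had it. Spearman correlations of log2 ratios with exon length and GC content across genes, which are not independent replicates, were 0.262 and 0.282 in HT29 and 0.0743 and 0.0290 in DLD-1. Python 3.11.15 with numpy 2.4.6, scipy 1.17.1, pandas 2.3.3 and matplotlib 3.10.9 did the remaining work.

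The rule of size, the list shifts within a line and the treatment term of the model were tested on simulated data. The line term, fry, the overlaps and the intron reads were not. The rule of size recovered 100% of genes simulated at 3-fold in each line, and its 1.5-fold form 98% of those at 1.75-fold in HT29 and 100% in DLD-1, with 0 unchanged genes called. List shifts of 1.5-fold were recovered in 100% of 50 lists, and 4.5% and 2.0% of 200 unchanged lists lay outside the central 95%. The simulations of the rule and of the lists held counting error only, with no variation between cultures. They therefore give no rate of false calls between real cultures. At a coefficient of variation of 10%, the model over both lines recovered 97% of genes at 2-fold and 100% at 4-fold; at 19.7% it recovered 43% and 100%. It called 8 unchanged genes at the former and 3 at the latter. This simulation gave each changed gene the same fold in both lines, took only genes with many reads, and used the same dispersion for all genes. Its recovery therefore does not hold for responses that differ in size between the lines, which the model counts as error.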

Results

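Gene expression was measured by RNA sequencing of polyadenylated RNA in HT29 and DLD-1, 2 established human colorectal adenocarcinoma cell lines. Cells of each line were deprived of serum and cultured for 3 days with DMSO, the vehicle, or with LDN-193189, a small molecule that inhibits the kinase activity of the type I receptors for bone morphogenetic proteins (BMPs). The dose was 0.2 µM in HT29 and 0.3 µM in DLD-1. The design gave 4 libraries, 1 for each line and treatment, so no group had replicates. The question was which genes change when BMP signaling is blocked in these cells, which themselves express BMP4. Exon reads over the 18329 genes of the tables came to 10073313 in HT29 with DMSO and 26472721 in HT29 with LDN-193189. They came to 23433365 in DLD-1 with DMSO and 24434270 in DLD-1 with LDN-193189. Reads over exon junctions made up 49.0% and 43.4% of exon reads in the DMSO and LDN-193189 libraries of HT29, and 37.3% and 43.3% in those of DLD-1. Mitochondrial mRNA took 3.50% and 2.75% of exon reads in HT29, and 4.58% and 2.93% in DLD-1.

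Within a line there was no test, and a gene was said to rise or fall only by a rule of size. Its ratio of RPKM + 1 had to reach 1.5-fold, the higher of its RPKM values had to be at least 3, and the 95% counting interval of its ratio of reads had to leave out 1. Ratios quoted for single genes are ratios of RPKM without the added 1, with that interval in brackets. The intervals cover counting error only, and a difference between 2 cultures has no replicate check here. For a gene list, the median log2 ratio of the members with an RPKM of at least 1 was set beside the medians of 10000 random lists of the same size and expression.

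ID1 fell with LDN-193189 in both lines, and ID2 and ID3 fell in DLD-1. ID1, a target of SMAD1 and SMAD5 whose product blocks differentiation factors, lies on chromosome 20 from 30193086 to 30194318 in hg19, the build of all positions here, and its values count reads in its exons. It fell from an RPKM of 214 to 70.2 in HT29, a 3.05-fold fall [2.90, 3.21], and from 207 to 17.9 in DLD-1, an 11.6-fold fall [10.7, 12.6]. ID3, on chromosome 1 from 23884409 to 23886285, fell from 81.4 to 7.48 in DLD-1, a 10.9-fold fall [9.82, 12.1], and had 10 and 14 reads in the libraries of HT29. ID2, on chromosome 2 from 8818975 to 8824583, fell from 100 to 46.9 in DLD-1, and its RPKM was 52.99 and 45.58 in HT29. Of the BMP target genes, 1 of the 6 measured members fell in HT29, ID1, and 4 of 8 fell in DLD-1, ID1, ID2, ID3 and the homeobox gene MSX1, which went from 16.5 to 8.97. No member of the list rose in HT29 or in DLD-1. The median log2 ratio of the list was −0.65 in DLD-1, below all of the random medians, and −0.19 in HT29, at percentile 4.61. BMP4, the ligand, on chromosome 14 from 54416454 to 54425479, had RPKM values of 261 and 246 in HT29 and of 325 and 295 in DLD-1, which did not pass the rule.

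**Figure D1:**
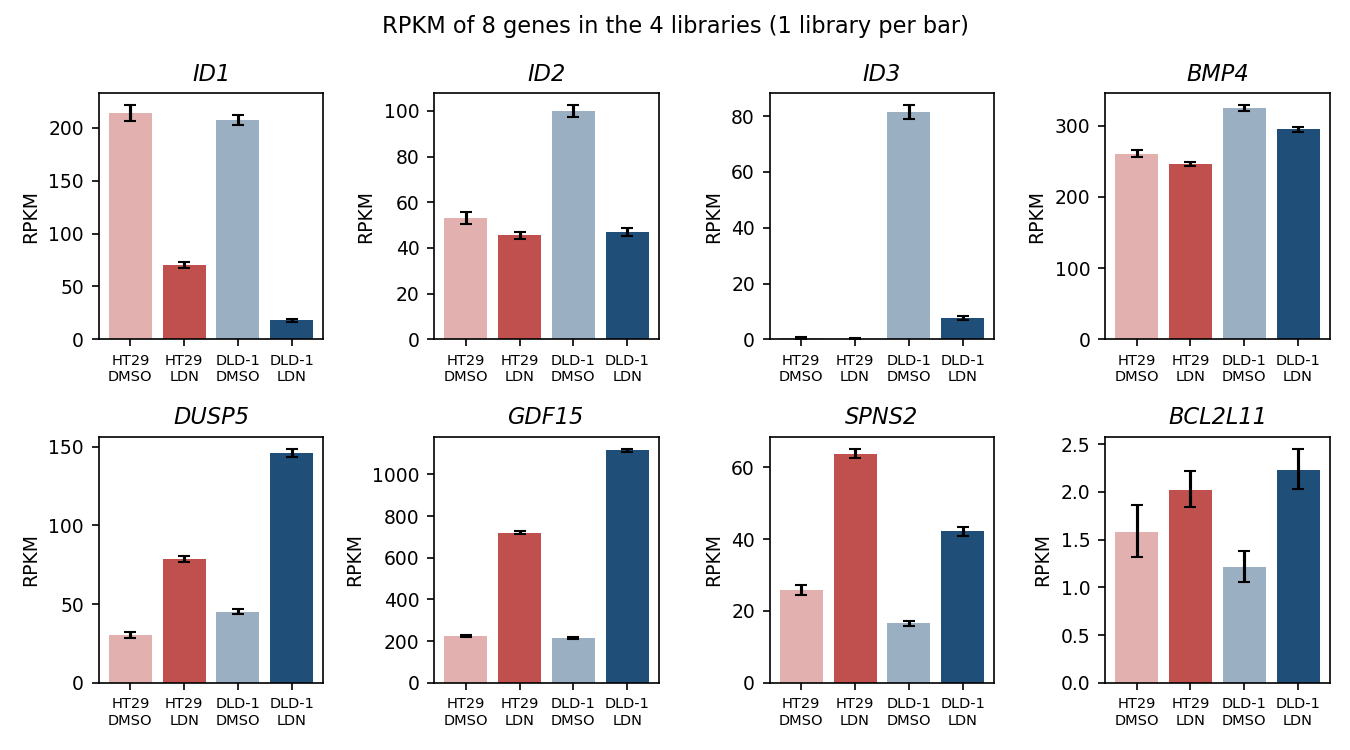
RPKM of 8 genes in the 4 libraries, 1 bar per library, with exact Poisson 95% intervals that cover counting error only; the vertical axes start at 0 and differ between genes. ID1 goes from 214 to 70.2 in HT29 and from 207 to 17.9 in DLD-1, while DUSP5, GDF15 and SPNS2 are higher with LDN-193189 (LDN) than with DMSO in each line.

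In HT29, the largest rises with LDN-193189 included BBC3, GDF15 and FASN, and the largest falls WNT11, TGFBI and CLIC3. BBC3, which encodes the pro-apoptotic protein PUMA, rose from an RPKM of 6.12 to 22.2, a ratio of 3.62 [3.12, 4.21]. GDF15, a stress-induced secreted factor of the TGF-β superfamily, rose from 224 to 721, 3.22-fold [3.13, 3.31], and FASN, the fatty acid synthase, rose from 53.6 to 156, 2.90-fold [2.82, 2.98]. The other genes among the 8 largest rises were TPPP3, PRSS22, KLF2, TRIM31 and FOSL1, with RPKM ratios from 2.69 for FOSL1 to 4.66 for KLF2. WNT11, a secreted Wnt ligand, fell from 15.6 to 0.549, a 28.5-fold fall [20.8, 39.8]. TGFBI, an extracellular matrix protein induced by TGF-β, fell from 9.02 to 0.908, 9.93-fold [8.59, 11.5], and CLIC3, an intracellular chloride channel protein, fell from 43.3 to 6.02, 7.20-fold [6.19, 8.40]. The 8 largest falls also held ID1, LINC00116, TOMM6 and FXYD6-FXYD2. The last 2 of these are uncertain, because no read of TOMM6 and at most 4.85% of the reads of FXYD6-FXYD2 mapped to it alone.

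Across the 6832 genes of HT29 that reached an RPKM of 3, 51 were higher and 31 lower past 2-fold, and 417 were higher and 204 lower past 1.5-fold. Under TMM rescaling of the 2 libraries the split past 1.5-fold became 321 higher and 262 lower, a share of higher genes of 55.1% in place of 67.1%, and under median-of-ratios rescaling 329 and 251, a share of 56.7%. In the authors' deposited tables, which use the RPKM ratio itself, 602 genes were higher and 279 lower past 1.5-fold, and 92 and 54 past 2-fold.

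Of the 14 measured genes of the integrated stress and unfolded protein response 8 rose in HT29 and none fell, among them the transcription factor ATF4, from an RPKM of 170 to 277, its target TRIB3, from 97.1 to 182, and the asparagine synthetase ASNS, from 21.5 to 35.1; the list median was 0.68, at percentile 100. Of the immediate early genes, transcription factors and regulators induced within minutes of growth factor signaling, 7 of 11 rose, among them IER2, whose ratio went from 1.69 to 1.47 on reads mapping to it alone, EGR1, from 8.50 to 18.4, FOSL1, from 31.7 to 85.1, and MYC, from 79.3 to 126, with a median of 0.74 at percentile 100. Of the dual specificity phosphatases, most of which remove phosphate from MAP kinases, 5 of 10 rose, namely DUSP1, DUSP2, DUSP5, DUSP8 and DUSP16, with a median of 0.66 at percentile 100. Among EGF family ligands and receptors the ligands AREG and HBEGF rose out of 8 members, with a median of 0.35 at percentile 98.8. AREG is uncertain, since 19.9% of its DMSO reads mapped to it alone. The NF-kB target genes had a median of 0.39 at percentile 98.4 with 1 of 7 risen, LCN2, and the epithelial genes one of 0.27 at percentile 97.6 with 1 of 10 risen, CLDN7.

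The lists of mitosis, DNA replication, histone and ribosomal protein genes lay below the central 95% of random medians in HT29. The mitosis genes had a median of −0.27 at percentile 0.01, and 2 of their 16 members fell, the cyclin gene CCNB1, from 51.1 to 27.2, and UBE2C, from 72.8 to 46.9. The DNA replication genes had a median of −0.27 at percentile 0.07, although only 1 of 15 passed the rule and that one, the licensing factor CDT1, rose from 22.0 to 33.9. Of the replication-dependent histone genes 4 of 10 fell, with a median of −0.22 at percentile 0.57, and of the ribosomal protein genes 1 of 24 fell, RPS19, with a median of −0.18 at percentile 0.91. On reads mapping to 1 place alone 4 ribosomal protein genes fell, with RPL7, RPL10 and RPS27 added. Less the trend of log2 ratios on GC content and exon length, which took up 15.5% of their variance in HT29, the histone list lay at percentile 19.0, the ribosomal list at 8.87 and the EGF family list at 91.95, all inside the central 95%, while the median of the DNA replication genes went to −0.11, at percentile 2.29, near the bound. Of the 4 histone genes that fell, HIST1H1C, HIST1H2AC and HIST1H2BD did not pass the rule less that trend, and HIST1H1E and HIST2H2AC rose. The epithelial list, near the bound, lay inside that range under most alternatives. Among these were TMM rescaling, at 97.3, the mean, at 96.2, and reads mapping to 1 place alone, at 94.5. The NF-kB list lay inside it with 5 added to each RPKM, at 92.5.

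The remaining lists lay inside the central 95% of random medians in HT29. Of 11 TGF-β and activin target genes, those that fell included TGFBI and PMEPA1, the latter from 66.6 to 30.7, and CDKN2B rose from 1.62 to 5.42 on reads of which 17.9% mapped to it alone in the DMSO library, where its RPKM stayed under 3 with a ratio of 2.55; the median was −0.16, at percentile 3.96. Of the ERK pathway output genes 2 of 9 rose, SPRY4 and EPHA2, with a median of 0.28 at percentile 94.1, and under TMM rescaling neither passed the rule. BBC3 alone rose among 10 pro-apoptotic BCL2 family genes, with a list median of 0.23 at percentile 93.7, and none of 7 anti-apoptotic genes passed the rule, at 74.5. BCL2L11, which encodes the pro-apoptotic protein BIM, had RPKM values of 1.58 and 2.02, a ratio of 1.28 [1.06, 1.57], under the RPKM minimum of the rule. Among 15 measured BMP ligands, receptors, mediators and antagonists BMP2 rose, from 5.29 to 9.95, with GDF15, and the list lay at percentile 58.1. SMAD4, the shared mediator, was low, at 0.309 and 0.433. Of 8 Wnt/β-catenin target genes SP5 rose and LGR5 fell, at percentile 5.33, and LGR5, from 8.01 to 3.87, was the 1 changed gene of 9 intestinal stem cell markers, at 27.2. SPDEF rose and REG4 fell, from 111 to 47.3, among 6 goblet cell markers, at 63.6, and none of 6 enterocyte and colonocyte markers changed, at 40.2. Of 7 p53 target genes SESN2 rose, at 79.2, the 16 cholesterol synthesis genes lay at 76.6, and of 13 hypoxia and glycolysis genes VEGFA rose, at 43.1. OAS1 fell among 6 interferon response genes, at 53.1, and neither the 4 Notch target genes, at 10.4, nor the 12 housekeeping genes, at 43.3, held a changed member. Of the 52 list members past the rule, TMM rescaling left 47 there and took out CDT1, CLDN7, EPHA2, SPDEF and SPRY4. Removal of the trend on GC content and exon length left 43, without CDT1, EPHA2, SPDEF, SPRY4, UBE2C, VEGFA and the 3 histone genes.

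In DLD-1, the largest rises with LDN-193189 included 2 metallothionein genes, GDF15 and NDRG1, and the largest falls were those of ID1 and ID3. MT2A, a metal-binding metallothionein on chromosome 16 from 56642111 to 56643409, rose from an RPKM of 37.2 to 336, a ratio of 9.03 [8.54, 9.56], and the neighboring MT1E rose from 17.7 to 117, 6.59-fold [6.01, 7.24]. At least 96.5% of the reads of these 2 genes mapped to them alone in DLD-1. GDF15 rose from 216 to 1115, 5.16-fold [5.06, 5.26], and NDRG1, a gene induced by hypoxia and metal stress, rose from 9.32 to 40.5, 4.35-fold [4.17, 4.54]. PRSS3P2 and PRSS1, members of the trypsin family, rose from 0.804 to 10.8 and from 0.783 to 6.94 on 30 and 41 reads with DMSO. RAB43 and ATF5 complete the 8 largest rises and are uncertain, since at most 1.91% and 28.1% of their reads mapped to them alone, with an RPKM on such reads under 3; the ratio of ATF5 on them was 2.62. After ID1 and ID3, the largest falls were those of GM2A, the activator of ganglioside breakdown, from 45.8 to 10.2, the transcription factor ZNF143, from 17.8 to 4.18, and PCP4, from 15.6 to 3.62. HCFC1R1 fell from 35.9 to 10.9, and TMEM141 and HSPA1A fell on reads of which at most 44.7% and 21.7% mapped to them alone.

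Across the 7522 genes of DLD-1 at an RPKM of 3 or more, 86 were higher and 76 lower past 2-fold, and 397 were higher and 510 lower past 1.5-fold. The balance depended on the scaling, since TMM rescaling gave 519 higher and 390 lower genes past 1.5-fold, a share of higher genes of 57.1% in place of 43.8%, and median-of-ratios rescaling 529 and 381, a share of 58.1%. Past 2-fold, these rescalings gave 112 against 51 and 113 against 48. By the authors' deposited RPKM ratio, 516 genes were higher and 711 lower past 1.5-fold, and 148 and 160 past 2-fold.

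Of the lists tied to growth factor signaling in DLD-1, 3 lay above the central 95% of random medians, and the EGF family list lay just inside it. Of the ERK pathway output genes 4 of 10 rose, the ETS factors ETV4, from 8.49 to 19.96, and ETV5, the receptor kinase EPHA2 and PHLDA1, with a list median of 0.55 at percentile 100. Of the immediate early genes 6 of 13 rose, including FOS, from 5.63 to 10.4, EGR1, from 56.7 to 87.7, and ATF3, from 4.60 to 10.1, with a median of 0.60 at percentile 100. The ratio of IER3, from 144 to 228, was 1.59, and 1.49 on reads mapping to it alone. On such reads DUSP1, at a ratio of 2.08, and the hypoxia gene ANKRD37, at 2.54, fell short of the RPKM minimum but not of the fold. The dual specificity phosphatases DUSP1, DUSP5 and DUSP8 rose out of 10, with a median of 0.45 at percentile 99.99. HBEGF, EGFR and ERRFI1 rose among 9 EGF family ligands and receptors, at percentile 97.2, or 99.0 by the mean and 98.4 with 5 added to each RPKM.

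Of the 13 measured hypoxia and glycolysis genes of DLD-1, the 6 that rose were NDRG1, ADM, ANKRD37, the glucose transporter SLC2A1, from 76.5 to 221, and the glycolytic enzymes LDHA, from 74.0 to 120, and PGK1, from 87.8 to 135, with a median of 0.49 at percentile 100. The replication-dependent histone genes had a median of 0.65 at percentile 100 with 5 of 10 risen, and the DNA replication genes one of 0.28 at 99.8, where none of 16 passed the rule. PCNA, the DNA clamp, stood at 117 and 176 and passed the rule under TMM rescaling, as did E2F1 and TYMS. Of 7 intestinal stem cell markers LGR5 rose, from 1.09 to 3.55, with ASCL2, from 46.0 to 75.6, and EPHB3, with a median of 0.46 at percentile 99.9, and the 11 Wnt/β-catenin target genes, which share LGR5 and ASCL2, had a median of 0.21 at 98.4. In the pro-apoptotic BCL2 family PMAIP1 rose and BIK rose, from 8.63 to 19.5, while BMF fell and BAX fell, from 63.5 to 37.9, out of 10, with a median of 0.31 at percentile 99.7 and a mean at 94.2. BCL2L11 had RPKM values of 1.21 and 2.23, a ratio of 1.84 [1.56, 2.17], under the RPKM minimum. The TGF-β and activin target genes had a median of 0.22 at 97.9, with SNAI1 and ANGPTL4 risen out of 9, and lay inside the central 95%, at 97.2, on reads mapping to 1 place alone.

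No other list of DLD-1 stood outside the random medians. The p53 target genes lay at percentile 96.1, or 98.2 on reads mapping to 1 place alone, with 4 of 9 risen, the cell cycle inhibitor CDKN1A, from 21.2 to 86.5, with PLK3, TP53I3 and BTG2. Of 10 epithelial genes the keratins KRT8 and KRT18 rose, at 88.8, VIL1 rose among 5 enterocyte and colonocyte markers, at 94.95, DLL4 among 6 Notch target genes, at 95.1, and LCN2 among 4 NF-kB target genes, at 89.3. CDC20 fell among 17 mitosis genes, at 13.2, MVD and FDPS fell among 15 cholesterol synthesis genes, at 10.9, and ISG15 fell, from 192 to 108, among 8 interferon response genes, at 14.5. RPL10, RPL37 and RPS27 rose among 24 ribosomal protein genes, at 33.8, and GDF15 among 19 BMP ligands, receptors, mediators and antagonists, at 77.4. On reads mapping to 1 place alone 3 ribosomal protein genes rose and 2 fell, RPL7 and RPS6. None of the 14 integrated stress and unfolded protein response genes changed, at 31.2, nor did any of 5 goblet cell markers, at 92.4, 6 anti-apoptotic genes, at 29.8, or 12 housekeeping genes, at 87.2. Of 57 list members past the rule, TMM rescaling left 55 there and took out CDC20 and FDPS, and removal of the trend on GC content and exon length also left 55, without EGFR and KLF6. SMAD4 stood at 3.01 and 3.02.

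Few markers of other cell types were measured. No enteroendocrine marker and no mesenchymal gene of the lists reached an RPKM of 1 in any library. Of the fibroblast markers 2 reached it in HT29, of which COL1A1 fell from 3.12 to 1.51, and 1 in DLD-1, which did not pass the rule. The leukocyte marker list held 1 such gene in each line, CD68, which did not pass the rule and of whose DMSO reads 12.3% in HT29 and 7.26% in DLD-1 mapped to it alone, and the endothelial list held none in HT29 and CLDN5 in DLD-1, at 1.65 and 1.32.

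**Figure D2:**
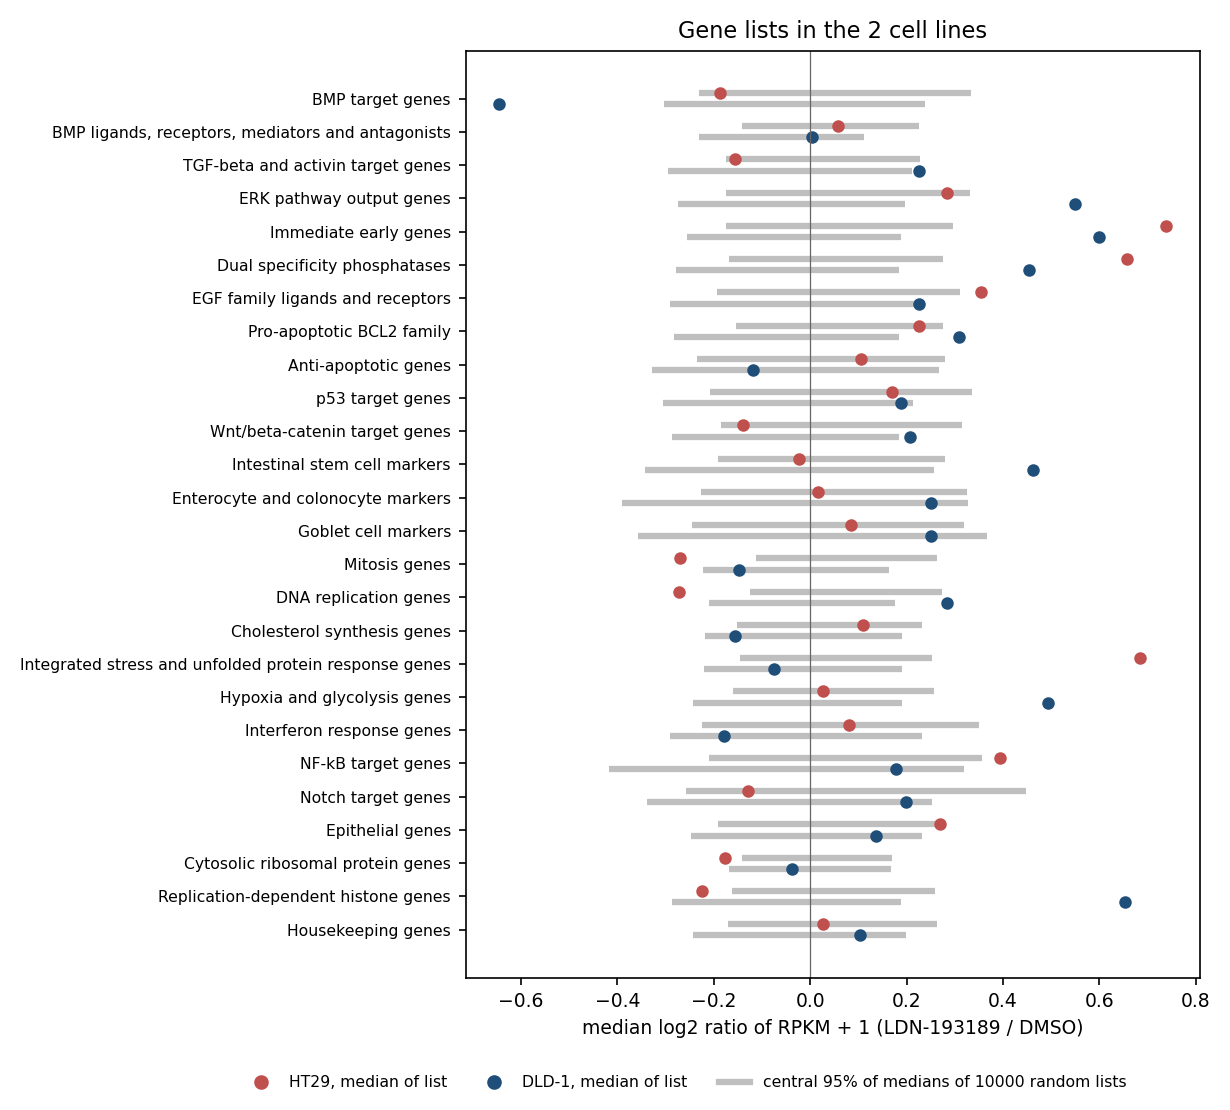
Median log2 ratio of RPKM + 1 (LDN-193189 over DMSO, horizontal axis) of the 26 gene lists with at least 3 measured members in each line, HT29 in red and DLD-1 in blue; grey bars span the central 95% of medians of 10000 random lists of the same size and expression. Immediate early genes and dual specificity phosphatases lie above the bars in both lines, BMP target genes lie below the bar in DLD-1, and DNA replication and histone genes lie on opposite sides in the 2 lines.

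Of the genes past 2-fold, 5 rose and 1 fell in both lines, among them DUSP5, SPNS2 and ID1. DUSP5, a nuclear phosphatase of ERK on chromosome 10 from 112257596 to 112271302, rose from 30.5 to 78.5 in HT29, 2.58-fold [2.41, 2.75], and from 45.1 to 146 in DLD-1, 3.24-fold [3.11, 3.36]. SPNS2, a transporter of sphingosine-1-phosphate, rose from 25.7 to 63.8 and from 16.5 to 42.1, and LCN2, a secreted iron-scavenging protein, from 52.6 to 108 and from 3.20 to 7.86. With GDF15 and FASTKD5 these made up the 5 genes past 2-fold upward in both lines, where independent lists would share 0.447; FASTKD5 is uncertain, with at most 11.6% of its reads mapping to it alone, and DUSP1, next in size, had at most 39.7%. ID1 was the 1 gene past 2-fold downward in both, where independent lists would share 0.121. Past 1.5-fold, and among the 6198 genes at the RPKM minimum in both lines, 42 genes were higher in both against 18.9 for independent lists, and 14 were lower in both against 8.196. The 14 included CLIC3, LMCD1, DCPS and MARCH2, besides PPAN-P2RY11, none of whose reads mapped to it alone. On reads mapping to 1 place alone the ratio of LMCD1 in HT29 was 0.288, against 0.341 on all reads, at an RPKM under 3, and that of MARCH2 in DLD-1 was 0.759 against 0.592. In the opposite sense, 17 genes were higher in HT29 and lower in DLD-1 against 19.1 for independent lists, and 21 were lower in HT29 and higher in DLD-1 against 8.10. Across these genes the log2 ratios of the lines had a Pearson correlation of 0.0762 and a Spearman correlation of 0.0786, and 52.1% had the same sign; genes are not independent replicates.

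**Figure D3:**
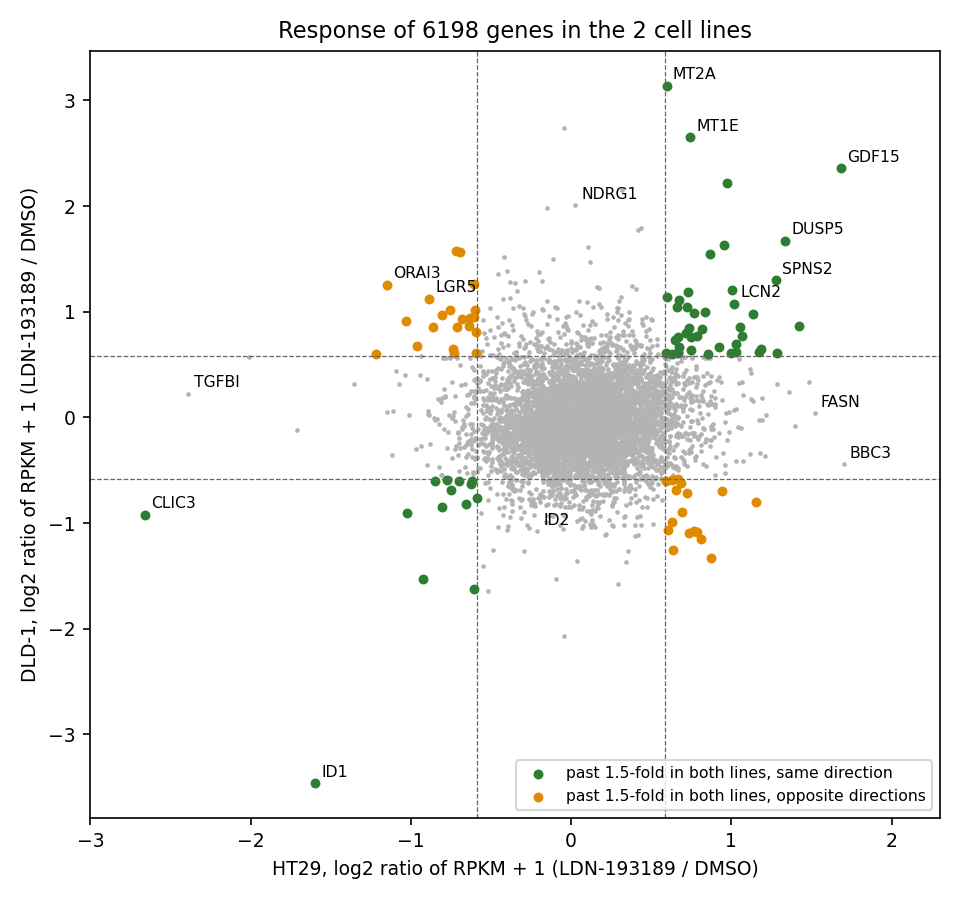
Log2 ratio of RPKM + 1 (LDN-193189 over DMSO) in HT29 on the horizontal and in DLD-1 on the vertical axis for 6198 genes, with dashed lines at 1.5-fold. Green points passed 1.5-fold in the same direction in both lines (42 higher, 14 lower) and orange points in opposite directions (17 and 21), and ID1, GDF15, DUSP5 and SPNS2 lie far out on the shared diagonal.

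When the 2 lines were used as replicates of the treatment, with cell line as a term of an edgeR quasi-likelihood model, no gene passed an adjusted p of 0.05. GDF15 was higher in the fit with LDN-193189 by a log2 fold change of 2.04 (SE 0.28), DUSP5 by 1.55 (SE 0.23) and SPNS2 by 1.35, while ID1 was lower at −2.55 (SE 0.41), ID3 at −2.83 (SE 0.48) and ID2 at −0.64 (SE 0.25). The lowest adjusted p of edgeR over 12482 genes was 0.433, which ID1, ID3, GDF15, SPNS2 and DUSP5 shared, while ID2 had 0.755. BCL2L11 had a log2 fold change of 0.64, SMAD4 one of 0.24 and BMP4 one of −0.10. The edgeR count of changed genes was 0, with 792 genes at an unadjusted p under 0.05, 515 of them higher and 277 lower. DESeq2 called 13 higher and 5 lower genes, edgeR without a filter on low counts 74 and 29, and limma on log2 RPKM + 1 none, with 617 at an unadjusted p under 0.05. The 13 higher genes of DESeq2 were AQP3, ATF5, CXCL5, DUSP5, GDF15, IRS2, ITPRIP, KLF2, LCN2, MT1E, MUC5AC, PLK2 and SPNS2, and the 5 lower ones included CLIC3, ID1, ID3 and TNFRSF11B, with adjusted p values in DESeq2 of 6.95e-10 for GDF15, 2.22e-07 for ID1 and 9.53e-06 for DUSP5. Some of these genes were close to absent in HT29, so that their values rest mainly on DLD-1. ID3 had 10 reads with DMSO and 14 with LDN-193189 in HT29. Reads of CXCL5, scaled to library size, were 0 and 0.124 in HT29, in the same order, and 9.87 and 44.05 in DLD-1. The model over both lines has 1 residual degree of freedom, counts any difference in response between the lines as error, and its doses differ with the line. In edgeR most of the error behind a p value is shared over genes, with 7.34 prior degrees of freedom. The p values do not measure a spread between replicate cultures.

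In the same model, the immediate early genes moved upward on balance as a list, with an adjusted p of 0.0174 by fry in limma over 28 lists and a median log2 fold change of 0.63. Adjusted over the list alone, 7 of its 15 genes were called, ATF3, EGR1, EGR3, FOSB, JUN, KLF6 and NR4A1, against 0 over all genes tested. The same count was 5 of 10 dual specificity phosphatases, DUSP1, DUSP2, DUSP4, DUSP5 and DUSP8, 4 of 8 goblet cell markers, FCGBP, MUC2, MUC5AC and SPDEF, and 3 of 10 BMP target genes, ATOH8, ID1 and ID3. It was 1 each for GDF15 among BMP ligands and receptors, HBEGF in the EGF family and LCN2 among NF-kB target genes. It was 0 in the other 21 lists, and over all genes tested it was 0 in each list. The lists of the model also held genes that stayed under an RPKM of 1 within a line. Of the goblet cell markers, 6 were measured in HT29, with SPDEF risen and REG4 fallen, and 5 in DLD-1, where none passed the rule of size. The BMP target genes had a median log2 fold change of −0.57 and an adjusted p of 0.613 by fry, and the next lowest adjusted p after the immediate early genes was that of the interferon response genes, 0.109, with a median of −0.23. For the TGF-β and activin target genes the median of −0.04 and the mean of 0.06 differed in sign, with an upward direction in fry and an adjusted p of 0.815. The test by fry says whether a list moves on balance one way and compares it with no other genes.

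Between the lines, in the same model, HT29 had higher TNFAIP2, an NF-kB target, with RPKM values of 31.2 and 45.9 against 0.107 and 0.150 in DLD-1, a log2 difference of 8.53 (SE 0.30). SLC17A9, a vesicular nucleotide transporter, had a log2 difference of 10.21 (SE 0.35). GPX2, AKR1B10, VSIG2, CSPG4 and CYP3A5 were also among the 8 lowest p upward, with 2 to 8 reads each in DLD-1. In the other direction TUBB6, a β-tubulin, had RPKM values of 0.605 and 0.663 in HT29 against 44.9 and 57.8, a log2 difference of −6.04 (SE 0.27). GSTM3, a glutathione transferase, had 0 reads in HT29 and was at least 3088-fold lower there, against a floor of 3 counts over the line. NGFRAP1, OLFML3, TMEM200A, QPRT and NLRP2 had 2 to 6 reads in HT29. The adjusted p of edgeR lay between 2.14e-06 and 2.25e-06 for these genes. SMAD4 was lower in HT29, at −2.71 (SE 0.25, adjusted p 7.51e-05 in edgeR), as was ID3, at −6.00 (SE 0.51). ID1 was higher in HT29 at 1.31 (SE 0.40, adjusted p 0.0271 in edgeR), with DMSO values of 214 and 207, and the call was lost without the treatment term, at an adjusted p of 0.553, and in limma, at 0.102, with 7.34e-06 the lowest over the alternatives. BMP4 did not pass, at 0.03 (SE 0.22), nor did DUSP5 at −0.42 or BCL2L11 at 0.42, although DUSP5 passed in limma with an adjusted p of 0.0300, against 0.476 as the highest over the alternatives. In all, 2836 genes were higher and 2838 lower in HT29 at an adjusted p under 0.05 of edgeR among 12482. Here the DMSO and LDN-193189 libraries of a line stood in for its replicates, with the same 1 residual degree of freedom. The split was 1856 and 3851 in limma on log2 RPKM + 1. Of the BMP target genes, 8 of 10 differed between the lines adjusted over the list alone and 8 over all genes tested, with 3 of these higher in HT29. No list moved on balance one way by fry, with a lowest adjusted p of 0.154, for the NF-kB target genes, whose median was 1.19, and the interferon response genes, whose median was −0.45.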

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

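The tests in this part that remove the trend on GC content and exon length, use reads mapping to 1 place alone or compare the ERK pathway output genes were chosen only after the result was seen, as was the use of rescaling, planned as an alternative, to test the balance, while thinning was chosen before. With 1 library per group, no difference between the lines in their response was tested, and values that go opposite ways in HT29 and DLD-1 are given as values.

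The medians of 2 lists went opposite ways in the lines, with a median log2 ratio of −0.27 in HT29 and 0.28 in DLD-1 for the DNA replication genes and of −0.22 and 0.65 for the replication-dependent histone genes. On reads mapping to 1 place alone the DNA replication list lay at percentile 0.03 of random lists in HT29 and 99.68 in DLD-1, and the histone list at 0.21 and 100, which argues against reads shared between paralogs. Less the trend on GC content and exon length, the lists of DLD-1 lay at 99.8 and 100, where the trend took up 1.17% of the variance and left little to act, while in HT29 the histone list lay at 19.04, its median going from −0.22 to −0.03, so that the trend may account for it. For the DNA replication genes in HT29 the median went from −0.27 to −0.11 and the percentile to 2.29, within sampling error of 2.5, so the trend and a response of the line cannot be told apart. The libraries were of polyadenylated RNA, so the histone values cover only polyadenylated transcripts of these genes. With LDN-193189 the share of exon reads over junctions also went opposite ways. That share fell from 49.0% to 43.4% in HT29 and rose from 37.3% to 43.3% in DLD-1, and its bearing on these lists was not tested. The dose and the line, which differ together, stay open and untested for DLD-1.

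The balance of genes past 1.5-fold went up in HT29, where 67.1% of 621 were higher, and down in DLD-1, where 43.8% of 907 were. TMM rescaling gave shares of 55.06% in HT29 and 57.1% in DLD-1, so the balance in DLD-1 turned and both lines leaned upward. The opposite balance of the lines thus depended on the scaling. TMM rescaling is 1 factor per library that brings the median of all genes near 0. The scaling and a change in most genes therefore cannot be told apart. Less the trend on GC content and exon length the share was 69.16% in HT29 and 44.48% in DLD-1. The trend was centred at 0, so its removal left the mean log2 ratio of these genes in place. These shares therefore cannot decide whether such a bias tilts the balance. In DLD-1 the trend also took up only 1.17% of the variance and left little to act. Thinning the deeper library of HT29 to 39.4% gave 68.45%. Thinning keeps the expected ratios and changes counting error only. It therefore argues against unequal counting error as the source there, and cannot decide on other effects of depth. In DLD-1 the depths themselves, 27976123 and 29253279 exon reads, left little difference to act, and thinning, which gave 43.83%, moved almost nothing and is no evidence of its own.

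Immediate early genes were higher in both lines. The lower of the 2 percentiles of the list was 100 less the trend on GC content and exon length and 100 on reads mapping to 1 place alone, which argues against either as the whole source. Handling at harvest can induce these genes within minutes. The slower ERK pathway output genes lay at 94.11 in HT29, or 98.01 by the mean, and at 100 in DLD-1. With 1 culture per group, handling and the inhibitor cannot be told apart.

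Past 1.5-fold, 17 genes were higher in HT29 and lower in DLD-1, and 21 were lower in HT29 and higher in DLD-1. Among the latter, the log2 ratio of RPKM + 1 was −0.81 in HT29 and 0.97 in DLD-1 for HIST1H1C, −0.68 and 0.93 for HIST1H2AC, −0.71 and 0.86 for HIST1H2BD, and −0.96 and 0.68 for HIST1H2BK. Less the trend on GC content and exon length, only HIST1H2BK of these 4 still passed in HT29. For LGR5 it was −0.89 and 1.12, and for ORAI3, a subunit of calcium channels and the 1 gene past 2-fold in opposite directions, −1.15 and 1.26.

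Reads in introns, which enter none of the RPKM values, were higher with LDN-193189 for DUSP5, GDF15 and SPNS2 in both lines. The ratio of intron reads, scaled to each library's intron total, was 3.46 [2.57, 4.77] in HT29 and 3.94 [3.29, 4.75] in DLD-1 for DUSP5. For GDF15 it was 3.01 [2.27, 4.06] and 2.05 [1.85, 2.27], and for SPNS2 it was 1.81 [1.43, 2.31] and 2.07 [1.74, 2.45]. Only ratios with an interval above 1 were flagged, so these genes alone are no check of the shared rises. Of the other genes past 2-fold upward in both lines, LCN2 had 3.90 [2.58, 6.15] in HT29 and 1.46 [0.764, 2.87] in DLD-1. FASTKD5 had 3 and 4 intron reads in HT29 and 0 and 3 in DLD-1, too few to judge.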

How the results depend on the processing

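The alternatives with reads mapping to 1 place alone and with log2 ratios less their trend on GC content and exon length were chosen after seeing the data. The balance of genes past 1.5-fold in DLD-1 turned, from 397 higher and 510 lower to 519 and 390 under TMM and 529 and 381 under median-of-ratios rescaling, each 1 factor per library. Less the trend, the histone genes of HT29 went from 0 risen and 4 fallen to 2 and 1, and under both rescalings the mitosis genes of DLD-1 went from 0 risen and 1 fallen to 1 and 0. No list median outside the central 95% and no ratio of a named gene past the rule of size changed sign, and where a value moved the cause was not tested. With 0.1 added to each RPKM in place of 1, 86 genes were higher and 51 lower past 2-fold in HT29 and 146 and 146 in DLD-1, with 22 genes lower in both lines past 1.5-fold and 29 higher in HT29 and lower in DLD-1. With 5 added, the counts past 2-fold were 17 and 14 in HT29 and 29 and 16 in DLD-1, and past 1.5-fold 174 and 69, and 185 and 186; the overlaps were 19 higher in both, 3 lower in both, 4 higher in HT29 and lower in DLD-1, and 8 the other way. With an RPKM minimum of 10, the lower genes were 17 past 2-fold and 108 past 1.5-fold in HT29 and 46 past 2-fold in DLD-1, where 238 were higher and 271 lower past 1.5-fold, and the overlaps were 25, 6, 7 and 13 in the same order. Median-of-ratios rescaling gave 48 lower genes past 2-fold in DLD-1 and 32 genes lower in HT29 and higher in DLD-1; TMM rescaling gave 32 of these and 11 the other way. Under the 2-fold rule the overlaps were 5, 1, 0 and 1. Over both lines DESeq2 gave 13 higher and 5 lower genes, and edgeR without a filter on low counts 74 and 29, where the main edgeR count was 0; between lines, limma gave 1856 genes higher in HT29. In all, 62 of 80 counts of changed genes, 27 of 44 overlap values and 19 of 24 counts from the models stayed within 1.5 times, or the spread, of the value reported. The condition on the counting interval took out no gene in either line. Counts of changed genes without that condition therefore equalled the main ones and say nothing of stability. Of 415 list medians under alternatives, 381 kept their side of the central 95% of random lists, 19 moved out of it and 15 into it. The goblet cell markers of DLD-1 lay at 99.1 with 5 added and 98.4 by the mean, its Notch list at 97.55 with 5 added and 99.1 less the trend, and its EGF family list at 99.2 over members at an RPKM of at least 3. Of the 52 list members past the rule in HT29 and 57 in DLD-1, 35 and 36 stayed past it with 5 added, and 43 and 44 with an RPKM minimum of 10. Of 505 ratios of named genes 148 moved beyond their counting interval, and of 180 tests of named genes in the models 11 passed the threshold newly and 2 no longer passed. Less the trend, the pro-apoptotic list of HT29 lay at percentile 99.2 and the Notch list at 1.82. By the mean, the BMP target genes of HT29 lay at 1.02 and the TGF-β and activin target genes at 0.09. The ERK pathway output genes of HT29 lay at 98.01 and its pro-apoptotic list at 97.92 by the mean, and the p53 target genes of DLD-1 at 99.98. The Pearson correlation between the lines ran from 0.0555 to 0.0844. Leaving out a library was not run, because each group has 1 and a model without a line has no residual degree of freedom. Depth limits the values of genes with few reads, above all in HT29 with DMSO.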

Other observations

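The tests on intron reads in this part were chosen before their result was seen, while MT1X and MT1F were chosen after their values were seen. Among metallothionein genes other than MT2A and MT1E, MT1X rose in DLD-1 from an RPKM of 6.43 to 25.8, and its values in HT29 were 1.70 and 2.16. MT1F had RPKM values of 6.27 and 5.46 in DLD-1. MT2A rose in HT29 from 8.32 to 13.1 and MT1E from 11.2 to 19.3. MT2A was near the 1.5-fold bound there, with a log2 ratio of RPKM + 1 of 0.596. Under TMM or median-of-ratios rescaling it fell short of that bound in HT29. KLF2, a transcription factor, rose in both lines, from 0.848 to 3.95 in HT29 and from 21 to 39 in DLD-1. BBC3, which rose in HT29, had RPKM values of 23.0 and 16.7 in DLD-1, and FASN had 329 and 338 there. NDRG1, which rose in DLD-1, had 181 and 185 in HT29.

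A change in transcription may underlie the genes past 2-fold, and it would carry their unspliced RNA along with the spliced. The median log2 ratio of intron reads was 0.88 over the 43 of 51 higher genes of HT29 with at least 20 intron reads, above all random gene sets, and −0.78 over 18 of 31 lower genes, below all of them. In DLD-1 it was 1.04 over 65 of 86 higher genes and −0.82 over 68 of 76 lower genes, again beyond all random sets. These genes were picked by exon reads of the same libraries. Intron reads of polyadenylated RNA can also come from the same transcripts as the exon reads. The comparison therefore cannot tell a change in transcription from other changes in RNA level. Counting intervals of intron reads left out 1 in the direction of the exon reads for 31, 13, 46 and 41 genes in that order, and in the other direction for 1, 0, 1 and 0. Single genes departed from this. WNT11, the largest fall of HT29 in exon reads, had an intron ratio of 0.943 [0.712, 1.26], and FASN, 2.90-fold higher in exon reads, one of 1.27 [1.11, 1.47]. In DLD-1, ZNF143 had 0.860 [0.600, 1.23] and PCP4 0.757 [0.482, 1.18]. Each value rests on 1 culture per group.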
